A study of Caenorhabditis elegans with 4 samples.

How the data were processed

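RNA was measured in 4 libraries of wild-type Caenorhabditis elegans (strain N2) early embryos. The embryos were a mixture of stages from the 1-cell to the 350-cell stage, taken per the labels from adults grown for 72 h after synchronization. Of the 4 libraries, 2 came from control RNAi (L4440, the empty RNAi vector) and 2 from RNAi against sig-7. Per the labels' protocols, 1 µg of total RNA was depleted of ribosomal RNA with a kit designed for human, mouse and rat, and stranded total RNA libraries were made. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the libraries of a group came from separate cultures, so any replicate spread behind the deposited p-values may be technical. The p-values of tests across genes do not measure the spread between libraries.

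Per the submitters' processing notes, the genome build was ce10 and the tools were FastQC, TopHat2, Cufflinks version 2.1.1 and Cuffdiff version 2.0.2. The parameters, the annotation and the use of strand are not given in the sources used here. The authors deposited a Cuffdiff table at each of 3 levels, with 37812 genes, 44542 isoforms and 38916 groups of isoforms that share a transcription start site (TSS groups). Per the file headers, each row holds an FPKM value (fragments per kilobase of transcript, normalized to the mapped fragments) for each group, the log2 ratio of sig-7 RNAi to control, a test statistic, a p-value and a q-value. The deposited FPKM is 1 pooled value per group. The spread between the libraries of a group and the depth of each library are therefore unknown, and no standard deviation, confidence interval or detection floor is given for an FPKM value. The replicate error enters only through the authors' deposited q-value.

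FPKM is a length-normalized unit, so a short RNA with few fragments can have a very high value, and a few such RNAs can take much of the total. In the gene table, 26913 rows were not tested by Cuffdiff and none of these exceeded 0.457 FPKM. A further 95 rows had too many fragments to be computed and are listed at 0 in both groups, and 101 rows failed. Among untested genes above 0, the product of FPKM and mature length in kb had a lowest cluster near 0.0177 in the control (488 genes) and near 0.0298 in sig-7 RNAi (940 genes). If that cluster stands for the same number of fragments in both groups, a fragment counted 1.68-fold more in sig-7 RNAi, and fewer fragments stand behind the same FPKM there. Whole fragments were not recovered, because the values are pooled estimates. The 10703 rows with status OK are the tested genes. Of these, 605 are listed at 0 in 1 group. The authors code their log2 ratio as infinite in such rows, and no fold is given for them here. The deposited log2 ratio equalled the ratio of the deposited FPKM values to within 1.43e-05 in the gene table. The significance flag in the gene table matched q < 0.05 in all 37812 rows. A q-value listed as 0 lies below the smallest value printed above 0, which was 1.37e-14. In 6 rows of the gene table the name had been turned into a calendar date by a spreadsheet, and these rows matched no list.

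A gene is said to have risen or fallen where its q in the authors' deposited table was under 0.05. Folds are the ratio of the pair of deposited FPKM values. Gene lists, length and chromosome comparisons used the 10507 tested genes with 1 gene name in the row. Before the data were examined, 31 gene lists, the tests and the rule for named genes had been fixed. Of 558 gene names in the lists, 531 were found, 17 of them by the sequence name of the gene. Further members were taken by name pattern (for example all col genes). For each of the 29 lists with at least 3 tested members, falls and rises in the list were compared with those of all other tested genes by a 2-sided Fisher's exact test, and the 58 p-values were adjusted by Benjamini-Hochberg. The median of log2((sig-7 RNAi FPKM + 1) / (control FPKM + 1)) was placed among 10000 random lists of the same size matched on mean FPKM in 20 bins. This scale, with its pseudocount of 1 FPKM, understates the change of low genes. Genes are not independent replicates, and the correlation between genes could not be estimated from pooled values, so the list tests describe these libraries.

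Gene spans, mature transcript lengths and RNA classes came from the WBcel235 annotation by gene name, with a match for 97.5% of the tested genes and 97.8% of those that rose or fell. WBcel235 is a later build than ce10, and no WBcel235 coordinate is given. The deposited locus of some genes is shorter than their annotated span, among them sig-7, unc-52, lev-11, elt-3, egl-44 and vab-3. The values of such genes may stand for part of the annotated gene, while the length comparison used the whole span. The locus in the deposited tables starts at base 0, since end minus start was 21 for 3801 loci holding a lone 21U RNA, and positions are given here from base 1 on ce10. Correlations of span with the log2 ratio are Spearman's rho across genes, with a 2-sided permutation p from 100000 permutations. Falls on the X chromosome and on autosomes were compared by Fisher's exact test, and within deciles of control FPKM or of span by the Mantel-Haenszel odds ratio.

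The rule for named genes took sig-7, then the 12 largest rises and the 12 largest falls among genes that passed q < 0.05 with at least 1 FPKM in both groups. From each list it took up to 4 members with the largest absolute log2 ratio among those that rose or fell with at least 1 FPKM in at least 1 group, and the member with the highest mean FPKM where fewer than 2 had changed. It selected 131 genes. Alternatives were q < 0.01, a fold of at least 2, a floor of 1 FPKM, rows with several names left out, rows listed at 0 left out, recentring to a median of 0, a pseudocount of 0.1 FPKM, unmatched random lists, and, chosen after the data were seen, scaling of both groups to the same total FPKM and leaving X-linked genes out of the lists. Equal total FPKM was applied as a common shift of the log2 ratios. It was also applied to the FPKM values before the pseudocount was added, for list medians and the length correlation.

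The list tests were tested on simulated log2 ratios for 10507 genes, with 10 changed and 20 unchanged lists of 20 genes. With noise of SD 0.25 or 0.4, the medians of 10 of 10 changed lists and of 0 of 20 unchanged lists lay outside the central 95% of random lists. The simulated genes were independent, with the same noise at all expression levels and no trend of the ratio with expression. The check therefore gives no rate of false calls for the real lists, whose genes may be correlated. Of the 6 lists changed by 1 on the log2 scale, 6 had more calls than other genes at SD 0.25 and 4 at SD 0.4. The length correlation, run on 10247 genes, gave a rho of 0.002 with no effect simulated and -0.274 with a simulated effect of span. The stratified X comparison, run on 10507 genes, returned an odds ratio of 2.784 where 3 had been simulated and 1.043 where expression alone acted. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.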

Results

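Total RNA from mixed early embryos was compared between RNAi against sig-7 (2 libraries) and control RNAi with the empty vector L4440 (2 libraries). SIG-7 is a nuclear cyclophilin with an RNA recognition motif that has been studied for its part in transcription elongation. The design asks which transcripts differ in level when sig-7 is depleted in the embryo. The authors' deposited tables give 1 pooled FPKM value per group, so values below have no spread of their own, the depth of each library is unknown, and the replicate error enters through the deposited q-value. Of 37812 gene rows, 10703 were tested.

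The target itself was lower in the knockdown. sig-7 (chromosome I, 8649759 to 8651583 on ce10, the locus given in the deposited table) was at 39.8 FPKM in control RNAi and 8.72 FPKM in sig-7 RNAi, so that 21.9% of the control level remained. The authors' deposited table gives a log2 fold change of -2.19 with q listed as 0. The gene, isoform and TSS group tables hold the same values for sig-7.

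Depletion of sig-7 was accompanied by changes in 3045 genes in the authors' deposited table, of which 1850 fell and 1195 rose. Falls were larger than rises. Among the genes that fell, 1549 were at least 2-fold lower and 884 at least 4-fold lower, genes listed at 0 in sig-7 RNAi included. Among those that rose, 362 were at least 2-fold higher and 39 at least 4-fold higher, genes listed at 0 in the control included. In 33 of the changed genes 1 group was listed at 0. The total FPKM was 1.69-fold higher in sig-7 RNAi, and the lowest step of its FPKM values was 1.68-fold larger. In sig-7 RNAi, the 10 rows with the highest values held 34.5% of the total, against 20.3% for the same rows in the control. They include the small nucleolar RNA gene ZK185.9 and the histone gene his-64, both named after their values were seen. With the pseudocount, the median log2 ratio over all tested genes with 1 name was -0.03, and scaling both groups to the same total would move every log2 ratio down by 0.754. Under that scaling, chosen after the data were seen, 811 of the 1195 rises kept their sign, while a fall cannot turn. List medians below are therefore mostly given relative to the median of all tested genes, which a common shift of the log2 ratios does not change. Scaling the FPKM values before the pseudocount is added moves low genes less than high ones, and was tried as a further alternative after the data were seen.

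Among the 12 largest falls were genes of matrix, lipid and transporter proteins. fbn-1, which encodes a fibrillin-like matrix protein (chromosome III, 7625321 to 7636321), was at 37.8 FPKM in the control and 1.71 FPKM in sig-7 RNAi, 22.1-fold lower. wrt-10, a hedgehog-related gene, was 17.2-fold lower (50.7 against 2.94 FPKM). F26F12.3 was 16.1-fold lower, M153.1 14.7-fold lower and C09F9.2 12.6-fold lower. The ABC transporter gene pgp-2 was 15.8-fold lower, and lrp-1, which encodes the megalin homologue, was 13.9-fold lower. fasn-1, the fatty acid synthase gene, was 14.3-fold lower, and pmt-2, a methyltransferase gene of phosphatidylcholine synthesis, fell from 34.2 to 2.70 FPKM. The remaining genes among the 12 largest falls were ceh-36, an Otx-class homeobox gene (14.4-fold), btb-11 (13.5-fold) and the UDP-glucuronosyltransferase gene ugt-23 (27.7 against 2.14 FPKM).

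Among the 12 largest rises were a histone gene, short noncoding RNA genes and pseudogenes. his-45, a histone H3 gene (chromosome IV, 11337831 to 11338241), was at 116.2 FPKM in the control and 1179 FPKM in sig-7 RNAi, 10.1-fold higher. T07F10.5 was 6.63-fold higher, from 4.25 to 28.2 FPKM. The small nucleolar RNA gene C17D12.8 rose from 1060 to 5895 FPKM, the noncoding RNA gene W05H9.3 was 6.27-fold higher, and C36C9.10, another, rose from 3189 to 16275 FPKM. F23A7.8, annotated as a coding gene of 204 bp, rose from 2763 to 14528 FPKM. Y80D4G.1 and F59H6.3, annotated as pseudogenes, were 5.32-fold and 5.25-fold higher. T04A6.5 was 5.11-fold higher, the F-box gene fbxa-114 4.83-fold, Y57G7A.2 4.56-fold and the long noncoding RNA gene linc-7 4.44-fold. The deposited locus of Y57G7A.2 holds 54 genes and its deposited q was 0.0376, so its value is less certain. The loci of T07F10.5 and C17D12.8 hold 3 and 2 genes and exceed annotated spans of 531 and 131 bp, so these values are less certain too. Core histone genes have near-identical copies, and how the authors divided shared reads is not given in the sources used here, so the value of a lone histone gene is uncertain.

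**Figure D1:**
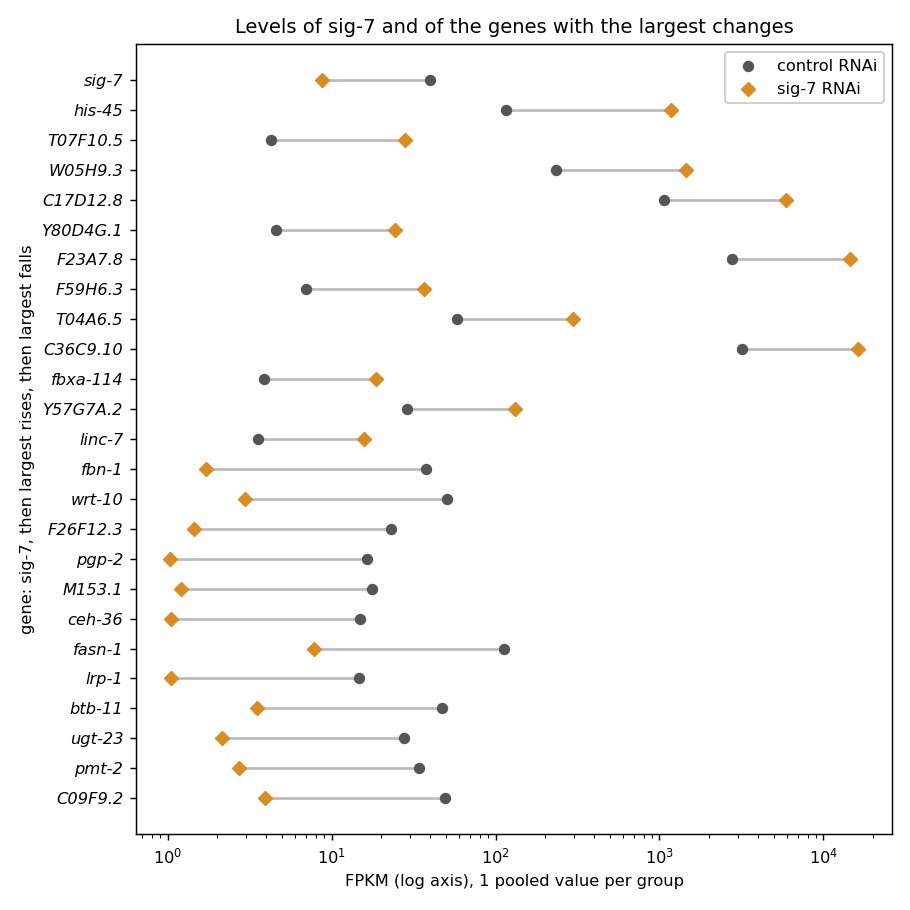
FPKM on a log axis for sig-7, the 12 largest rises and the 12 largest falls, with a circle for the pooled control value and a diamond for the pooled sig-7 RNAi value (no error bars, since each group has 1 pooled value). sig-7 moves from 39.8 to 8.72 FPKM, fbn-1 from 37.8 to 1.71 and his-45 from 116.2 to 1179.

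Epidermal and body wall muscle genes fell more often than other genes. Of 17 tested epidermal genes, 12 fell and 0 rose (12 and 0 adjusted over the list alone). noah-1 and noah-2, which encode apical matrix proteins of the epidermis, fell 10.3-fold and 8.54-fold from 110.2 and 98.8 FPKM. elt-3, an epidermal GATA factor gene, was 12.6-fold lower, from 3.18 to 0.252 FPKM, and its deposited locus is shorter than its annotated span. The list median lay 1.75 below that of all tested genes, below all 10000 matched random lists (percentile 0), and falls were more frequent than among other genes (Fisher's exact test, adjusted p = 1.21e-05). Of 27 tested body wall muscle genes, 17 fell and 1 rose (17 and 2 adjusted over the list alone), with an adjusted p of 1.56e-06 for falls by Fisher's exact test and a median 0.99 below all genes (percentile 0.095). The perlecan gene unc-52 was 7.81-fold lower, the tropomyosin gene lev-11 6.41-fold, the troponin I gene unc-27 5.16-fold and the myosin heavy chain gene unc-54 4.02-fold lower, all from control values of 5.19 FPKM or less. The deposited loci of unc-52 and lev-11 are shorter than their annotated spans of 37136 and 9926 bp, so these values may stand for part of each gene.

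In the intestinal and neuronal lists an excess of falls passed the main test but not every alternative. Of 10 tested intestinal genes, 6 fell and 0 rose (7 and 0 adjusted over the list alone; Fisher's exact test for falls, adjusted p = 0.0118). Their median was at percentile 2.93 of matched lists, inside the central 95%, and at 0.48 with FPKM scaled before the pseudocount. elt-2, the GATA factor gene of the intestine, went from 6.37 to 1.09 FPKM, the protease gene cpr-6 from 5.79 to 0.765 FPKM, the intermediate filament gene ifb-2 was 3.57-fold lower and the protease gene asp-1 3.39-fold lower. Of 27 tested neuronal genes, 11 fell and 0 rose (13 and 0 adjusted over the list alone; Fisher's exact test for falls, adjusted p = 0.0127), with a median at percentile 1.25. Besides ceh-36, the TEAD-family gene egl-44 was 11.2-fold lower, at 0.632 FPKM in sig-7 RNAi. The homeobox genes lin-11 and unc-86 were 4.85-fold and 4.84-fold lower, from control values of 1.01 and 2.03 FPKM. The excess of falls in both lists was lost at q < 0.01 and with X-linked genes left out, and that of the neuronal list also with a floor of 1 FPKM. Without X-linked genes fewer were left to test, 3 of 7 and 7 of 21 fell, and the median log2 ratios were -0.87 (percentile 7.68) and -0.77 (percentile 1.86), against -0.96 and -0.77 with them. Of 10 tested pharyngeal genes, 2 fell (2 adjusted over the list alone; Fisher's exact test, adjusted p = 0.794). Their median was at percentile 3.53, at 2.27 with FPKM scaled before the pseudocount and at 1.02 without X-linked genes. The genes that fell were pha-4, the FoxA gene of pharyngeal identity, at 26.9 and 8.87 FPKM, and tbx-2, 3.54-fold lower. Of 12 tested cilium genes, 1 fell (1 adjusted over the list alone; Fisher's exact test, adjusted p = 0.801), and the RFX factor gene daf-19, which did not pass the test, was at 6.06 and 4.95 FPKM.

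Of 35 tested cuticle collagen genes, 10 fell and 0 rose (10 and 0 adjusted over the list alone). The excess of falls missed the threshold over the whole list (Fisher's exact test, adjusted p = 0.201), but passed it with a floor of 1 FPKM. The list median was not low for genes of like expression (percentile 51.7 of matched lists, 79.4 without X-linked genes and 95.2 with FPKM scaled before the pseudocount). The 10 included highly expressed members, with dpy-17 at 215.7 and 22.8 FPKM and sqt-3 at 122.3 and 9.94 FPKM, while col-99 was 13.7-fold and dpy-2 9.52-fold lower.

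Falls were more frequent than among other genes in the homeobox, nuclear hormone receptor and detoxification lists, although many of their genes did not pass the test. Of the 53 tested homeobox genes outside the tissue lists, 23 fell and 1 rose (24 and 3 adjusted over the list alone; Fisher's exact test for falls, adjusted p = 4.45e-05), with a median at percentile 0.01. The Pax6 gene vab-3 was 11.1-fold lower, ceh-26 9.78-fold, pax-3 9.26-fold and ceh-27 8.78-fold lower. In sig-7 RNAi, vab-3, ceh-26 and pax-3 were at 0.730, 0.362 and 0.926 FPKM. Of the 116 tested nuclear hormone receptor genes outside the tissue lists, 43 fell and 2 rose (49 and 3 adjusted over the list alone; adjusted p = 2.91e-06 for falls by Fisher's exact test), an excess that was lost at q < 0.01. Their median was at percentile 4.83, inside the central 95% of matched lists, and at 0.24 with FPKM scaled before the pseudocount. nhr-67 went from 7.08 to 0.340 FPKM, while nhr-79, nhr-94 and nhr-172 started from 1.51, 2.68 and 1.00 FPKM and were at or below 0.262 FPKM in sig-7 RNAi. Of 64 tested detoxification genes, 32 fell and 2 rose (33 and 3 adjusted over the list alone; Fisher's exact test for falls, adjusted p = 2.25e-08). Their median was at percentile 0.72, and at 3.40, inside the central 95%, with FPKM scaled before the pseudocount. The glucuronosyltransferase genes ugt-4, ugt-57, ugt-65 and ugt-11 were 19.5-fold to 27.1-fold lower from control values of 1.36 to 5.19 FPKM.

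F-box genes were divided by family. Of 190 tested, 74 fell and 16 rose (76 and 17 adjusted over the list alone; Fisher's exact test for falls, adjusted p = 4.10e-11), with a median at percentile 0 of matched lists. In the fbxb family 52 of 106 fell and 1 rose, and in the fbxc family 19 of 33 fell and 4 rose, whereas in the fbxa family 3 of 51 fell and 11 rose. The fbxa median of 0.28 turned to -0.47 with the groups scaled to equal total FPKM, and the medians of the fbxb and fbxc families stayed below 0. The split into families was made after the values were seen, and the difference between them was not tested. fbxb-96 went from 17.7 to 0.780 FPKM, fbxc-19 from 9.62 to 0.458 FPKM, fbxb-30 from 6.34 to 0.304 FPKM and, against the direction of most fbxa calls, fbxa-46 from 5.48 to 0.242 FPKM. Many F-box and glucuronosyltransferase genes have close paralogues, so their values may share reads.

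Genes of the splicing, proteasome, polymerase and histone lists rose more often than other genes, with list medians that turn below 0 when the groups are scaled to equal total FPKM. Of 39 tested splicing factor genes, 22 rose and 0 fell (22 and 0 adjusted over the list alone; Fisher's exact test for rises, adjusted p = 2.57e-10). The Sm protein genes snr-5 and snr-4 were 2.61-fold and 2.32-fold higher, prp-38 was 2.59-fold and ddx-23 2.36-fold higher. Of 32 tested proteasome genes, 19 rose and 0 fell (21 and 0 adjusted over the list alone; Fisher's exact test for rises, adjusted p = 1.34e-09), among them pas-5 (2.05-fold), pbs-4 (1.84-fold), rpn-12 (1.84-fold) and pbs-7 (1.77-fold). Of 31 tested genes of RNA polymerase II and elongation, 13 rose and 1 fell (15 and 1 adjusted over the list alone; Fisher's exact test for rises, adjusted p = 7.51e-05). Among polymerase subunit genes, rpb-12 went from 228.2 to 570.5 FPKM, and rpb-7 and rpb-4 were 2.21-fold and 2.11-fold higher, while fcp-1, the gene of the phosphatase of the polymerase tail, was 2.48-fold higher. Of 41 tested core histone genes, 17 rose and 3 fell (17 and 3 adjusted over the list alone; Fisher's exact test for rises, adjusted p = 6.08e-06). Besides his-45, his-18 went from 1290 to 3590 FPKM and his-53 from 0.0626 to 5.44 FPKM, and his-21, at 3.41 FPKM in the control, was listed at 0 in sig-7 RNAi. Near-identical histone copies may share reads, so the calls in this list may not be separate measurements, and its p-value and percentile count them as if they were.

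Of 42 tested cell cycle genes, 13 rose and 2 fell (17 and 4 adjusted over the list alone; Fisher's exact test for rises, adjusted p = 0.00237). The replicative helicase genes mcm-6, mcm-3 and mcm-5 were 2.27-fold, 1.96-fold and 1.91-fold higher, whereas cya-1, a cyclin A gene, was 2.16-fold lower. The excess of rises was lost in the cell cycle list at q < 0.01, and in the cell cycle and proteasome lists with the groups scaled to equal total FPKM. The medians of these 5 lists lay 0.48 to 0.74 above that of all tested genes, and 0.27 to 0.52 above it with FPKM scaled before the pseudocount. Under equal total FPKM the cell cycle median too turned below 0. Highly expressed genes in general had higher ratios, and against random lists of like expression only the histone median (percentile 99.3) and the splicing median (percentile 98.6) lay above the central 95%. The proteasome (78.0), polymerase (85.7) and cell cycle (57.6) medians did not.

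Ribosomal protein genes had a lower median than genes of like expression. This was not particular to them. The unfolded protein response list (percentile 0.01 of matched lists) and the genes with the prefixes vha (1.18) and cct (1.24) were also low, whereas the proteasome list (78.0) was not. Of 75 tested, 9 fell and 4 rose (8 and 4 adjusted over the list alone), and neither count passed the test (Fisher's exact test, adjusted p = 0.237 for rises). Their median log2 ratio of -0.06, close to that of all tested genes, was lower than in all matched random lists (percentile 0), whose own median was 0.61. Paralogues of 1 protein went opposite ways, with rpl-11.2 at 144.0 and 36.7 FPKM and rpl-11.1 at 63.4 and 128.0 FPKM. The deposited locus of rpl-11.2 holds 90 genes, against 1 for rpl-11.1, so the rpl-11.2 value is less certain. rpl-25.1 was 2.98-fold and rpl-3 2.21-fold lower.

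Genes of the unfolded protein responses and of signalling fell more than they rose. Of 16 tested unfolded protein response genes, 7 fell and 1 rose (8 and 1 adjusted over the list alone; Fisher's exact test for falls, adjusted p = 0.0402), an excess that was lost at q < 0.01. Of these genes 5 are X-linked and all 5 fell, and with X-linked genes left out 2 of 11 fell, which did not pass the test (Fisher's exact test, adjusted p = 0.795). The median was at percentile 0.01 of matched lists, and at 0.30 without X-linked genes. dve-1, atf-6 and pek-1 were 5.40-fold, 2.11-fold and 1.94-fold lower, and ubl-5 was 3.71-fold higher. Of 25 tested Notch and Wnt genes, 9 fell and 0 rose (9 and 0 adjusted over the list alone). The excess of falls missed the threshold (Fisher's exact test, adjusted p = 0.0785) but passed it with X-linked genes left out (adjusted p = 0.0189), and the median lay at percentile 0.06 of the matched lists. The Wnt gene cwn-2 was 8.57-fold lower, the Notch receptor gene lin-12 5.52-fold, the Frizzled gene cfz-2 3.21-fold and gsk-3 2.98-fold lower. Of 15 tested heat shock genes, 5 fell and 0 rose (5 and 0 adjusted over the list alone; Fisher's exact test for falls, adjusted p = 0.255). Their median was at percentile 9.69 of matched lists, and at 0.02, outside the central 95%, with FPKM scaled before the pseudocount. Among them, hsp-70 was 4.15-fold and hsp-12.2 5.15-fold lower, hsp-1 was at 303.6 and 206.4 FPKM and C30C11.4, the hsp-110 gene, at 133.0 and 93.0 FPKM.

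In the other fixed lists neither falls nor rises passed Fisher's exact test with adjustment. Of 46 tested early zygotic genes, 8 fell and 1 rose (8 and 1 adjusted over the list alone). Among these, sdz-28 went from 99.5 to 10.2 FPKM, and sdz-18, sdz-2 and sdz-19 were 7.13-fold, 5.20-fold and 4.64-fold lower. The deposited locus of sdz-28 holds 9 genes, so its value is less certain. Of 30 tested maternal germline genes, 3 fell and 3 rose (2 and 2 adjusted over the list alone). cgh-1 and car-1 were 2.09-fold and 1.79-fold lower, and nos-2 and meg-1 were 1.70-fold and 1.66-fold higher, meg-1 turning below 0 on the log2 scale under equal total FPKM. Of 14 tested eggshell genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone), namely chs-1 (1.63-fold) and cpg-2 (1.57-fold), both of which also turned under that scaling. Of 18 tested genes of dosage compensation and sex determination, 6 fell and 2 rose (6 and 2 adjusted over the list alone), with sdc-2 4.21-fold, sdc-3 2.80-fold, dpy-21 2.17-fold lower and dpy-27 at 73.2 and 33.3 FPKM. Of 28 tested chromatin genes, 5 fell and 6 rose (6 and 8 adjusted over the list alone), and hda-1, hpl-1, mep-1 and lin-13 were 1.83-fold to 2.18-fold lower. Of 34 tested small RNA pathway genes, 3 fell and 6 rose (3 and 6 adjusted over the list alone), with the Argonaute gene alg-1 2.19-fold lower and drh-1, nrde-4 and nrde-1 2.05-fold, 1.82-fold and 1.70-fold higher. Of 19 tested DNA damage genes, 3 rose and 0 fell (2 and 0 adjusted over the list alone), namely msh-2 (2.22-fold), rpa-1 (1.98-fold) and hus-1 (1.77-fold). Of 24 tested oxidative phosphorylation genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone), among them ucr-2.3 (1.96-fold), nuo-6 (1.81-fold), cyc-2.1 (1.79-fold) and cco-1 (1.57-fold, turning under equal total FPKM). Of 23 tested lectin and lysozyme genes, 4 fell and 3 rose (4 and 3 adjusted over the list alone). clec-196 was 3.12-fold and cnc-10 2.71-fold lower, clec-91 was 2.40-fold higher, and clec-157, at 1.35 FPKM in the control, was listed at 0 in sig-7 RNAi.

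Markers of adult tissue were near the floor in both groups. None of the 5 yolk protein genes was tested, and the highest stood at 0.0757 FPKM in the control and 0.159 FPKM in sig-7 RNAi. Of the sperm genes 2 were tested and neither passed, with nspd-5 listed at 0 in the control and at 0.761 FPKM in sig-7 RNAi.

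**Figure D2:**
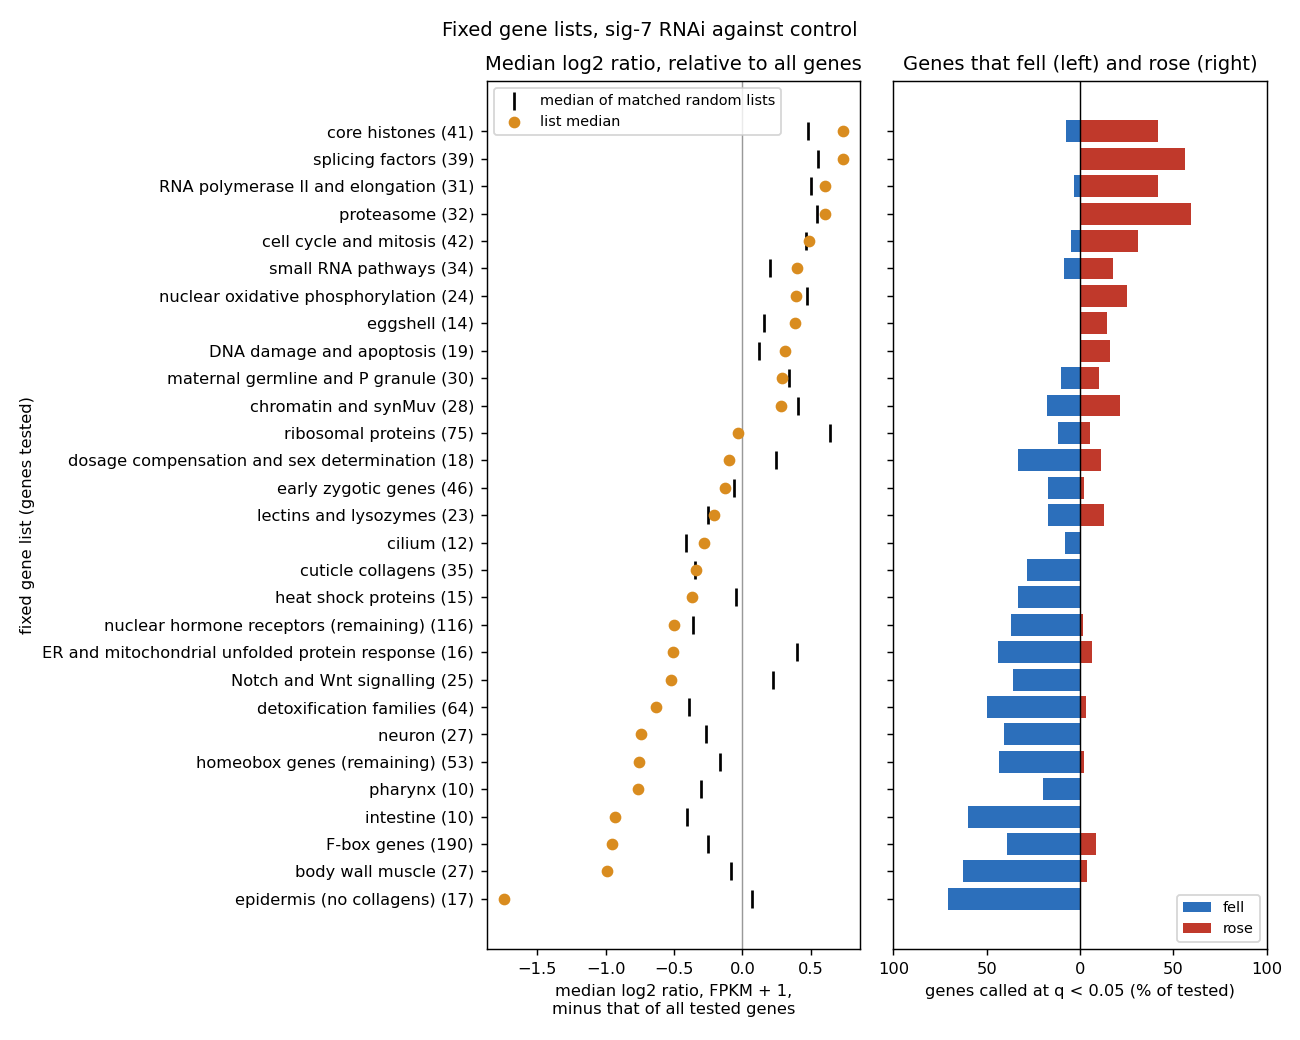
Left, median log2 ratio of each fixed list (circle) and of matched random lists (tick), both minus the median of all tested genes, on a scale of log2((sig-7 RNAi FPKM + 1) / (control FPKM + 1)). Right, the percentage of tested members that fell (to the left) and rose (to the right) at q < 0.05, with the number tested in parentheses at each name. The epidermal list lies lowest, 1.75 below all genes, and the histone and splicing lists lie highest, 0.74 and 0.73 above, although their medians themselves turn below 0 when the groups are scaled to equal total FPKM.

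Longer genes had lower ratios. sig-7 has been studied for elongation, for which gene length is a natural comparison. Across 10247 tested genes with a span in the annotation, span and log2 ratio were correlated with a Spearman's rho of -0.20 (p = 1e-05, the smallest that the permutations can give). The span is that of the whole annotated gene, whereas the deposited locus of some genes is shorter. For unc-52 the span was 37136 bp and the locus ran from 14647404 to 14650962 on chromosome II. No alternative used the length of the locus. Among genes of up to 1024 bp, 4.48% fell and 14.8% rose, and among genes of 5219 bp or more, 26.9% fell and 4.93% rose. The correlation was negative within each quintile of mean FPKM, from -0.06 in the lowest to -0.29 in the highest. Genes are not independent replicates, and the test describes these libraries.

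The direction of change varied with the expression level. In the quintile with the highest mean FPKM, 34.5% of genes rose and 7.02% fell. In the quintile between 1.02 and 5.75 FPKM, 1.90% rose and 29.1% fell. In the lowest quintile 0.98% rose and 16.1% fell, so calls of falls did not become steadily more frequent towards low expression. These shares also depend on which low genes were tested and on the power to call them, which may differ between rises and falls. That power cannot be given, since depth is unknown. The median log2 ratio was 0.51 in the highest quintile, -0.24 under equal total FPKM, and it was -0.60 in the quintile between 1.02 and 5.75 FPKM and -0.42 in the lowest. The pseudocount understates the change in the low quintiles.

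Genes on the X chromosome fell more often than autosomal genes. Of 1469 tested X-linked genes, 505 fell (34.4%) and 57 rose (3.88%). Of 9038 autosomal genes, 1299 fell (14.4%) and 1127 rose (12.5%). The odds ratio for falls was 3.12 (95% interval 2.75 to 3.53, Fisher's exact test, p = 3.66e-68), and that for rises was 0.283. The share that fell on single autosomes ran from 10.9% on chromosome I to 18.7% on chromosome V. The median log2 ratio was -0.54 on X and 0.07 on autosomes, the latter -0.68 under equal total FPKM.

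**Figure D3:**
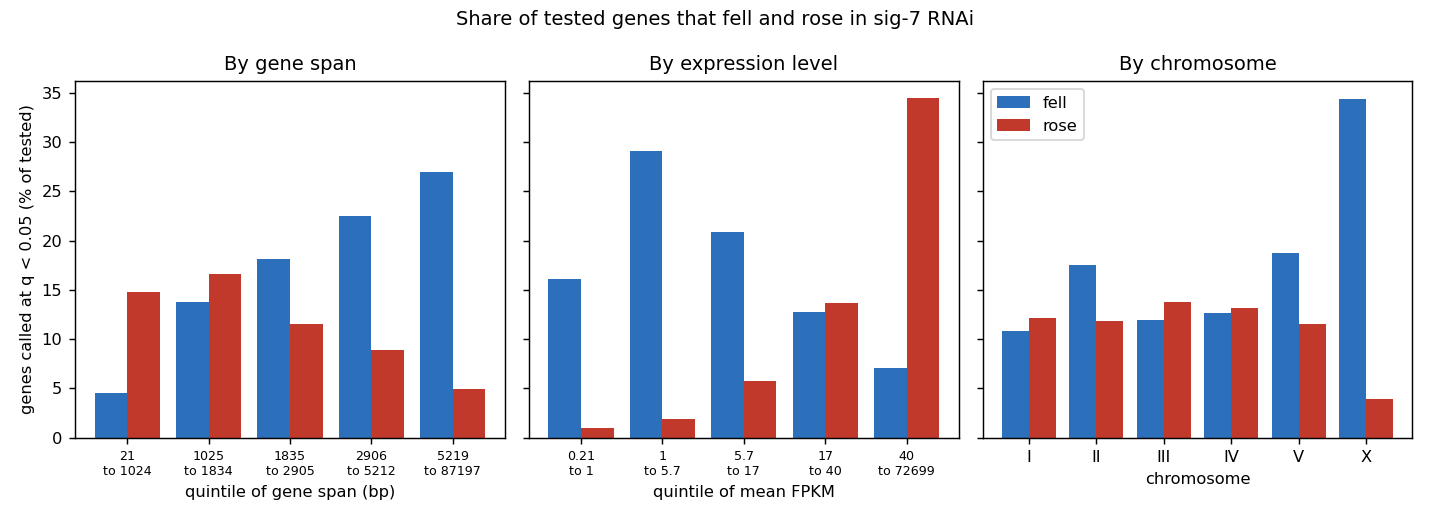
Percentage of tested genes that fell and rose at q < 0.05 by quintile of gene span in bp (left), quintile of mean FPKM (middle) and chromosome (right), with bars from 0. Falls go from 4.48% in the shortest to 26.9% in the longest quintile of span, rises reach 34.5% in the highest quintile of expression, and 34.4% of X-linked genes fell.

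The isoform and TSS group tables gave similar counts. In the authors' deposited tables, 1836 of 11176 tested isoforms fell and 1195 rose, and 1792 of 10629 tested TSS groups fell and 1174 rose. Of the 3031 isoforms that rose or fell, 2940 belonged to a gene that changed the same way. Most genes had 1 tested isoform, and 525 genes had several. A lone tested isoform may carry most of the value of its gene, which was not examined. In 13 genes an isoform rose while another fell, and 11 of these did so under equal total FPKM. At q < 0.01 there were 5 such genes, named here after their values were seen, namely trr-1, F37D6.2, F47B7.2, F54B3.1 and ceh-100. In trr-1, the TRRAP homologue (chromosome II, 11661736 to 11675792), an isoform listed at 0 in the control was at 11.1 FPKM in sig-7 RNAi, while the others that changed were 2.53-fold and 4.16-fold lower. In ceh-100 an isoform went from 18.9 to 37.8 FPKM and another from 9.23 to 2.48 FPKM. In F54B3.1 an isoform was 1.92-fold higher and another 2.55-fold lower. In F37D6.2 an isoform went from 33.1 to 64.4 FPKM and another from 12.2 FPKM to a listed 0, and in F47B7.2 an isoform went from 21.4 to 5.44 FPKM and another from a listed 0 to 2.06 FPKM. No gene had TSS groups that changed in opposite directions (0 of the 52 genes with several tested TSS groups).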

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

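Scaling to equal total FPKM (as a shift of the log2 ratios or before the pseudocount), leaving X-linked genes out of the lists, the scalings of the opposite isoforms, the restriction of the length correlation to coding genes and the stratified X comparison were chosen after the data were seen, and the other alternatives before. The count of changed genes kept within 1.5 times of 3045 under q < 0.01, a floor of 1 FPKM, several names left out and rows at 0 left out, and falls outnumbered rises in each. Recentring and q recomputed over the tested rows moved no call, so they test nothing here. Under equal total FPKM 2661 calls kept their sign, a shift that can turn rises only. With a fold of at least 2 required as well, 1911 genes, 1945 isoforms and 1859 TSS groups remained, fewer by construction. The number of genes with opposite isoforms went from 13 to 5 at q < 0.01, where fewer isoforms pass. The number of lists with more falls or rises than other genes went from 14 to 9 at q < 0.01, where fewer genes pass. It was 14 with the floor and 12 with equal total FPKM. That scaling can turn rises only, so the 9 lists with more falls stayed, while 3 of the 5 with more rises did. The number was also 12 with X-linked genes left out. There the intestinal, neuronal and unfolded protein response lists, with fewer genes tested, lost their excess of falls and the Notch and Wnt list gained one. The number of list medians outside the random lists was 11, 14 with FPKM scaled before the pseudocount (intestine, pharynx, heat shock and nuclear hormone receptors gained, detoxification lost), 12 with X-linked genes left out (pharynx gained), and 17 when random lists were not matched on expression, in line with the rise of the ratio with expression level. Under equal total FPKM all 11 list medians above 0 turned below 0, by either way of scaling. Among the lists with a called change, the medians of the histone (-0.043), splicing (-0.045), polymerase (-0.17), proteasome (-0.18) and cell cycle (-0.30) lists reversed with the shift and were -0.033, -0.032, -0.16, -0.15 and -0.28 with FPKM scaled before the pseudocount. The shift also reversed meg-1 (-0.022), chs-1 (-0.049), cpg-2 (-0.10) and cco-1 (-0.10). Of the named genes with a fold, 124 kept their sign under equal total FPKM and 15 missed q < 0.01. The length correlation stayed negative and past its threshold in all alternatives (-0.29 to -0.06, and -0.24 with FPKM scaled before the pseudocount), and the X odds ratio was 3.55 with the floor and 2.97 within deciles of control FPKM. No paired analysis was possible because the tables hold 1 pooled value per group, and for the same reason no library could be left out. Depth is unknown, so precision at low FPKM cannot be given. The lowest step of FPKM was 1.68-fold larger in sig-7 RNAi. If that step stands for the same number of fragments in both groups, low genes are measured less finely there.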

Other observations

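Other gene groups moved as well. The families in this paragraph were taken from shared name prefixes after the data were seen, for the 71 prefixes outside the fixed lists with at least 8 tested genes, and adjusted over these. Of 13 tested patched-related genes (ptr), 10 fell and 0 rose (Fisher's exact test for falls, adjusted p = 0.000534), with ptr-23 going from 10.6 to 0.938 FPKM and a median at percentile 4.25 of matched lists, inside the central 95%. Of 18 cuticlin-like genes (cutl), 11 fell and 0 rose (Fisher's exact test, adjusted p = 0.00257), with cutl-2 at 14.5 and 1.75 FPKM and a median at percentile 0.87. Of 11 peroxin genes (prx), which serve peroxisome assembly, 7 fell and 0 rose (Fisher's exact test, adjusted p = 0.0153), with prx-5 12.6-fold and prx-1 11.9-fold lower and a median at percentile 2.49. Of 16 innexin genes (inx), which encode gap junction proteins, 8 fell and 0 rose (Fisher's exact test, adjusted p = 0.0409), with inx-5 14.5-fold lower and a median at percentile 4.62, inside the central 95%. Of 8 FK506-binding protein genes (fkb), a family of prolyl isomerases distinct from the cyclophilins, 6 fell and 1 rose (Fisher's exact test, adjusted p = 0.0147), with fkb-3 going from 29.4 to 4.96 FPKM and a median at percentile 0.16. Of 20 nucleoporin genes (npp), 9 rose and 0 fell (Fisher's exact test for rises, adjusted p = 0.00532), with npp-13 1.92-fold higher. Their median was at percentile 69.2 of matched lists, inside the central 95%, and turned from 0.50 to -0.25 under equal total FPKM. The prefixes daf and unc, named for phenotypes and not for protein families, also held more falls than other genes.

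Small nucleolar RNAs took up part of the rise in total FPKM. Over 130 tested genes of this class the summed FPKM went from 51894 to 152454, 2.94-fold, against 2.34-fold for the 553 genes annotated as ncRNA and 1.45-fold for the 9372 coding genes. Only 5 of the 130 rose at q < 0.05 and 0 fell. Most of the gain came from the highest of these genes, ZK185.9, which went from 33285 to 112113 FPKM, and the sum over the other 129 rose 2.17-fold. The median log2 ratio of the class was 0.50, and -0.26 under equal total FPKM.

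In the paragraphs that follow, the tests were chosen after the patterns had been seen, and those of scaling, of adult tissue, of embryo age and of expression level against gene length also after their own results had been seen. The lower levels of tissue genes in sig-7 RNAi have technical and developmental explanations to weigh. A scaling error between the groups would shift all lists by at most the size of the error, but the highest and lowest list medians lay 2.48 apart, and 2.26 apart with FPKM scaled to equal total before the pseudocount. A common shift leaves this gap unchanged, so the gap shows that lists differed from each other and not that the scaling was right. Adult tissue carried into the control would bring yolk transcripts, whose highest value was 0.0757 FPKM in the control and 0.159 FPKM in sig-7 RNAi. A younger mix of embryos in the knockdown libraries could lower tissue genes too. It would leave early zygotic genes relatively high, and their median was at percentile 34.8 of matched lists, so this and an effect of sig-7 depletion on tissue genes cannot be told apart, since the stage mix of each library is not known.

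The excess of falls on the X chromosome may reflect properties in which X-linked genes differ. Within deciles of control FPKM the odds ratio was 2.97 (95% interval 2.62 to 3.37), and within deciles of gene span it was 3.33 (95% interval 2.92 to 3.80), so neither lower expression nor greater length accounts for it alone. The products of the dosage compensation genes lower X expression, so a loss of them would raise it, the opposite of the falls seen. In the list that holds these genes, 6 of 18 fell and 2 rose, but 3 of those that fell, sdc-2 among them, are X-linked themselves. Without X-linked genes 3 of 13 fell and the list median went from -0.12 to 0.22, so the count partly restates the pattern. It remains open whether X-linked genes are richer in genes transcribed later in the embryo, for which the age of the embryos matters as above.

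Longer genes had lower ratios, as would be seen if depletion of an elongation factor slowed long genes, which is a hypothesis here. Expression level did not account for it (partial rho -0.22 given mean FPKM, 95% bootstrap interval -0.24 to -0.20). The correlation remained with the members of the fixed lists left out (rho -0.21 over 9162 other genes, interval -0.23 to -0.19). The tissue lists are short, so other tissue genes may have stayed in. Whether the age of the embryos, open above, bears on gene length was not tested. Given both mature transcript length and mean FPKM, the partial rho of span was -0.085 (interval -0.11 to -0.07), and that of mature length given span and mean FPKM was -0.053 (interval -0.07 to -0.03). In simulated data where span alone acted, the partial rho of mature length given span was -0.001. That value follows from the design of the simulation, which left out mean FPKM, so it is no measure of the -0.053. The partial rho of span lay between the bounds set for the test, so a bias that follows transcript length, such as one in library preparation, could account for part of the relation, and the share due to span and to transcript length cannot be told apart.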
